A study of Mus musculus with 65 samples.

How the data were processed

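Chromatin accessibility of newly replicated DNA was measured in mouse E14TG2a embryonic stem cells by repli-ATAC-seq. Per the labels, 20 uM EdU was given for 10 min, followed where stated by a chase with 10 uM thymidine for 30 min, 1 h or 2 h, and DMSO, DRB or triptolide was given for 2 h before EdU. Drug doses, and whether the drug stayed on during the chase, are not given in the sources used here. DRB blocks CDK9 and triptolide blocks the XPB subunit of TFIIH, which is textbook knowledge and not from the labels. The RNA polymerase II S5P samples carried 2.5% of Drosophila S2 chromatin, and the spike-in samples 100 EdU-labelled S2 cells, per the labels. The labels do not say which libraries come from separate cultures, so p-values measure the spread between these samples.

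The submitters' processing notes name Trim Galore 0.4.2 and Bowtie2 2.2.6.2 and the build mm10, without parameters. The peak caller is not given in the sources used here. The deposited peak lists hold positions only (start and end of each peak, 1 list per group), with no height, so the depth behind them is unknown. Replicates had been combined by the authors. The inhibitor tables hold, per the file headers, log2(RPM + 1) computed by the authors in 1 kb windows every 500 bp (5451088 windows on 22 chromosomes, 36 libraries). RPM was recovered from these deposited values by undoing the log2, and read numbers by dividing by the smallest step of each library. In every inhibitor library 100% of values were whole reads within 0.1 read. The deposited spike-in tables hold log2 values for 5 kb regions at TSSs and enhancers. A single read stands for 1.09 and 2.28 in the nascent and 1.24 and 1.32 in the 2 h libraries, and 27458 non-overlapping TSS regions sum to between 58.2% and 182% of the total that defines RPM, so these values are not plain RPM. How the S2 reads entered is not given in the sources used here.

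Without duplicates there were 32004 TSS regions, of which 31995 had full length and a window, and 8794 enhancers. For each TSS and enhancer the 1 kb window nearest its centre was used. Background was 20000 windows drawn (seed 20190128) from 3855267 windows with a read in some library and at least 1000 bp from the peaks of any list. TSSs were named from a RefSeq gene table for the same build within 1000 bp of the gene end that the strand of the TSS gives, which paired 25743 TSSs with 25176 symbols, 19344 TSSs with protein-coding genes. Of these TSSs 821 had more than 1 gene within reach, and 736 coding genes were paired with a TSS inside the gene. For a gene with several TSSs the one with the highest mean was kept. Neighbouring genes can share a window, and copies of histone, small nuclear RNA, olfactory receptor and Zscan4 genes are near-identical, so their names are uncertain.

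The step of a single read in each library gave totals between 1.30 M and 5.55 M reads in the EdU and between 2.35 M and 14.4 M in the unbound libraries. Reads have no molecular identifiers, so intervals cover counting error only. The share of reads on the X chromosome was 1.91% to 2.49%. No column of the tables was left out.

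TSSs and enhancers above 0 in at least 3 libraries (2 for the spike-in) were tested on log2 values with limma 3.58.1 (moderated, with a trend) in R 4.3.3, all groups of a fraction in 1 fit, with Benjamini-Hochberg adjustment within each of 23 comparisons and a threshold of 0.05. The median standard error of a log2 difference was 0.33 in EdU, 0.17 in unbound and 0.55 in spike-in data. Differences between effects (2 h minus nascent, EdU minus unbound) were contrasts in the same fits. Means of TSSs, enhancers and background were compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p under 0.1 nor 2 against 2 one under 0.33. Peak overlaps of at least 1 bp were counted and compared by Fisher's exact test, two-sided, and shares have Wilson 95% intervals. Steady-state peaks within 1000 bp of a TSS were TSS peaks, the rest were enhancer peaks if they overlapped the central 1 kb of an enhancer, else other peaks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and, in R, data.table (version 1.17.8) were used. edgeR and DESeq2 were not used here.

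The 13 gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the first set of alternatives. With the members paired with a TSS they were pluripotency genes (34), immediate early genes (23), p53 targets (20), housekeeping genes (25), Polycomb-bound developmental regulators (66), ribosomal protein genes (81), replication-dependent histone genes (62), olfactory receptor genes (1013) and markers of primitive endoderm (13), trophectoderm (8), fibroblasts (11), the 2-cell-like state (11) and neural and germ layers (12). Some genes stand in more than 1 list. Fos, Egr and Hox symbols follow the RefSeq table, and members without a TSS within reach, such as Egr1, Tet1 and Eef1a1, were not used here. Lists were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 13 lists of a comparison. Camera compares a list with all other genes, so a list can stand higher than the rest while its median is near 0. With an estimated correlation the calls that held were ribosomal protein and olfactory receptor genes (nascent triptolide), olfactory receptor genes (nascent DRB), housekeeping, ribosomal protein, histone and olfactory receptor genes (2 h triptolide), p53 targets, ribosomal protein and olfactory receptor genes (2 h DRB) and histone and olfactory receptor genes (2 h against nascent).

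Genes named in the text were, per main comparison, the 8 with the largest difference in each direction among those that passed the threshold, had no overlap between the libraries of the groups and at least 1 RPM in one of them, then the 2 members of each list with the largest difference, then fixed markers (Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Myc, Fos, Actb, Gapdh and Gata6). Some genes that the rule names are not reported here. Genes with names of predicted genes, microRNAs, clones or the Snor family were passed over. Chance alone separates a share of 0.1 of features in 3 against 3 libraries. Genes named outside the rule are said to be chosen after their values were seen.

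Alternatives were a pseudocount of 0.25 in place of 1, no filter, a filter at a mean of 1 RPM, each library centred on its median tested feature, libraries scaled to background windows, a fit of only the groups compared, the replicate number as a block, the mean of windows within 1 kb, and each library left out in turn. For peaks they were an overlap of at least 0.5 of each peak, the steady-state peaks wider than the median and a TSS distance of 500 bp. Added after the data were seen were limma-voom on the recovered reads, which called 2889, 91, 10833 and 1153 TSSs for nascent triptolide, nascent DRB, 2 h triptolide and 2 h DRB and 9877 for 2 h against nascent, and the ratio of mean signal to mean background. Replicate numbers were checked for pairing by correlating what is left of each library after its group mean. No comparison had every correlation of like numbers above 0.1, so the numbers were not taken as pairs.

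Calling was tested on data simulated from the control libraries, with 200 TSSs changed. Adjustment depends on how many TSSs change, so recovery in the real comparisons can differ. Of 50 TSSs changed at each size, limma recovered 28% of 0.25-fold, 4% of 0.5-fold, 14% of 2-fold and 76% of 4-fold changes at nascent depth, with 7.58% false among 66 calls. At 2 h depth it recovered 64%, 28%, 26% and 92%, with 0 false among 105 calls, and in spike-in data 46%, 12%, 44% and 90%, with 0 false among 96. With an added variance of 0.15 set by hand between 0% and 34% were recovered. The variance added beyond counting was 0.001, the smallest the simulation took, since the control libraries gave no larger one. A simulated list lowered 1.5-fold had a camera p of 3.6e-09, 1.6e-25 and 9.1e-13 in the 3 data sets (simulated libraries, not an exact test), and one not moved 0.34, 0.99 and 0.28. A brute-force check of overlaps on 2000 intervals had 0 disagreeing. EdU-labelled S5P chromatin is not analysed here.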

Results

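The series holds 65 samples in 24 groups of mouse embryonic stem cells of the E14TG2a line, grown on gelatin with serum and LIF. Repli-ATAC-seq labels newly replicated DNA with EdU, cuts accessible chromatin with the Tn5 transposase, and captures the labelled fragments on streptavidin beads. Cells received EdU for 10 min and were taken at once (nascent chromatin) or after a thymidine chase. Steady-state cells were untreated and stand for accessible chromatin of the whole population. In the inhibitor experiment cells were kept for 2 h before the pulse in DMSO, in DRB (an inhibitor of the CDK9 kinase, which RNA polymerase II needs for elongation) or in triptolide (an inhibitor of the XPB subunit of TFIIH, which it needs for initiation). Both the EdU fraction and the unbound supernatant of the capture were sequenced, in 3 libraries per group. A separate pair of groups, nascent and 2 h, had 100 EdU-labelled Drosophila S2 cells added per sample, with 2 libraries each. The time series (3 samples per time) is 1 combined peak list per time, of unknown depth and without replicates. A peak list of RNA polymerase II phosphorylated on serine 5 (S5P), from 2 samples of total chromatin, was also used. S5P of EdU-labelled chromatin is not analysed here.

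The EdU libraries of the inhibitor experiment held between 1.30 M reads (nascent DRB replicate 2) and 5.55 M (nascent triptolide replicate 3). The unbound libraries held between 2.35 M (nascent DMSO replicate 2) and 14.4 M. In nascent DMSO chromatin 54.4% to 55.1% of the signal lay outside peaks, against 32.6% to 37.7% at 2 h. The spike-in libraries held between 572346 and 1863396 reads in TSS regions, with 15 to 36 reads in the median region.

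The peak lists of the time series ask when after replication each accessible site of the whole population comes back. The nascent list held 47341 peaks, and the lists at 30 min, 1 h and 2 h held 72247, 87051 and 106983, against 166636 at steady state. Of the steady-state peaks, 20.6% were overlapped by the nascent list (Wilson 95% interval 20.4% to 20.7%), then 37.0%, 46.1% and 57.8%. Peaks within 1000 bp of a TSS led, with 49.9% of 21678 in the nascent list and 78.3% in the 2 h list. Enhancer peaks began low and caught up with them. Of 8077 enhancer peaks, 21.8% were in the nascent list, 54.9% at 30 min, 69.5% at 1 h and 79.1% at 2 h, against 15.8% and 53.3% of the 136881 other peaks in the nascent and 2 h lists. TSS peaks that carried S5P were in the nascent list in 80.8% of 5279 cases, and TSS peaks without S5P in 6556 of 16399 cases, or 51.3% and 24.8% where at least 0.5 of each peak had to overlap. Fisher's exact test, two-sided, gave an odds ratio of 6.34 for that difference, with p at the smallest value written, 1e-300, and 3.19 with the stricter overlap (p = 7.0e-272). TSS peaks had an odds ratio of 5.30 against other peaks and enhancer peaks had 1.48 (Fisher's exact test, two-sided, p = 3.8e-42 for the latter). The enhancer difference was lost where at least 0.5 of each peak had to overlap (odds ratio 1.05, Fisher's exact p = 0.18). Peaks are not independent replicates, and lists of more deeply sequenced samples are longer, so the growth of the lists cannot be separated from depth.

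**Figure D1:**
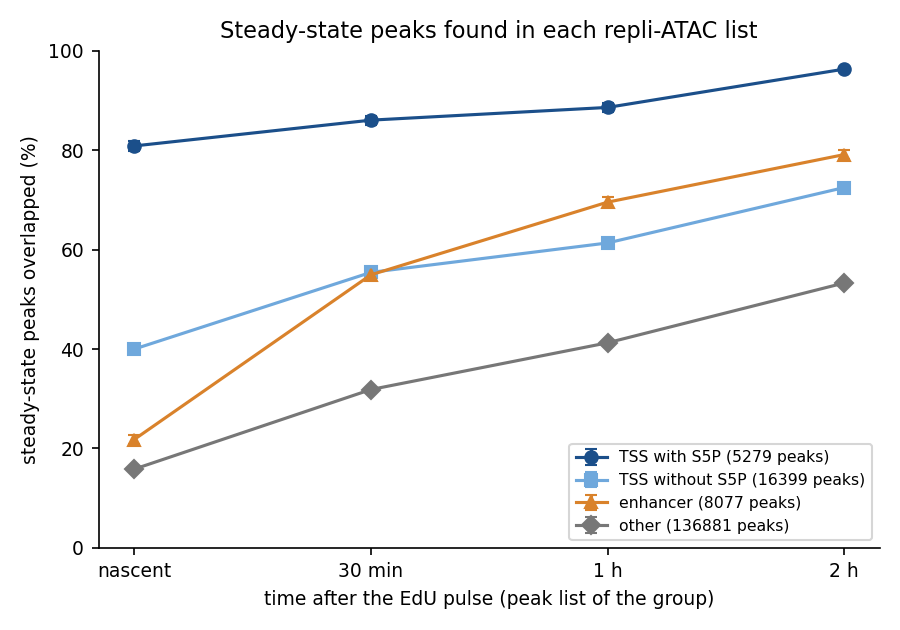
Share of steady-state peaks (%) overlapped by the peak list of each time, for TSS peaks with and without S5P, enhancer peaks and other peaks; bars are Wilson 95% intervals. TSS peaks with S5P start at 80.8% and enhancer peaks pass from 21.8% to 79.1%.

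Among the fixed gene lists, immediate early genes, which respond first to serum and growth factors, had a nascent peak at 22 of 23 TSSs. Pluripotency genes had one at 26 of 34, housekeeping genes at 20 of 25, p53 targets at 17 of 20 and ribosomal protein genes at 69 of 81. Replication-dependent histone genes had a nascent peak at 23 of 62 TSSs and a peak at 54 of 62 by 30 min, and 54 of 62 carried S5P. Polycomb-bound developmental regulators had a peak at 21 of 66 in the nascent list, 34 at 30 min, 36 at 1 h, 51 at 2 h and 62 at steady state. Olfactory receptor genes, silent in these cells, had a peak at 1 of 1013 TSSs in the nascent list and 28 at steady state. Primitive endoderm markers went from 5 to 11 of 13, trophectoderm markers from 4 to 7 of 8, fibroblast markers from 2 to 8 of 11 and neural and germ layer markers from 4 to 12 of 12. Markers of the 2-cell-like state had no peak at any time, of 11. Pou5f1, Nanog, Sox2, Klf4 and Zfp42, core factors of pluripotency, had a peak from the nascent list on, as did Myc, Actb, Gapdh and Gata6. Fos appeared first at 30 min, and Esrrb had no TSS peak in any list.

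The comparison of 2 h with nascent DMSO chromatin asks how accessibility returns in the 2 h after the fork has passed. The ratio of mean TSS signal to background, a measure chosen after the values were seen, was 5.29 ± 0.10 in nascent and 18.7 ± 2.05 in 2 h EdU libraries (SD, n = 3 each), a 3.54-fold difference. At enhancers it was 4.35 ± 0.15 and 24.5 ± 3.59 (SD, n = 3 each), a 5.63-fold difference. No library of one time overlapped the other (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). In the unbound fraction the ratio was 23.1 ± 0.80 and 21.0 ± 2.11 at TSSs, and 28.4 and 27.7 at enhancers. Mean TSS signal was 1.13 ± 0.04 and 1.58 ± 0.03 (mean of log2(RPM + 1), SD, n = 3 each, exact permutation p = 0.1), and mean enhancer signal 1.03 ± 0.03 and 2.05 ± 0.06.

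**Figure D2:**
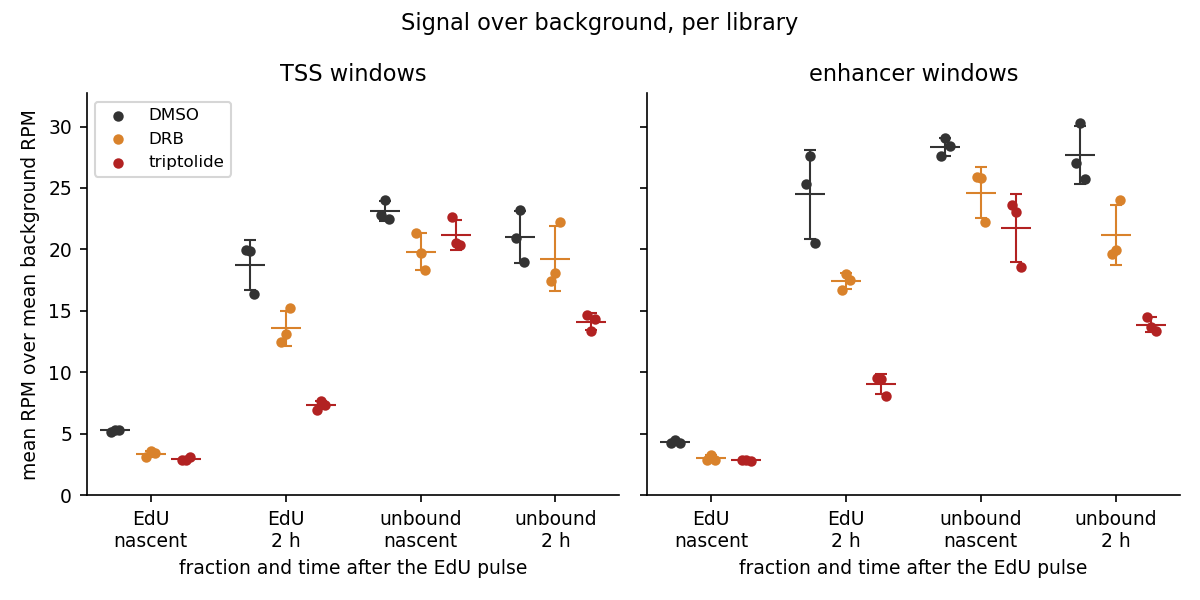
Mean RPM of TSS windows (first panel) and enhancer windows (second panel) over mean RPM of background windows, a ratio without unit, for each library (points) with the mean and SD of each group (n = 3). EdU-captured TSSs go from 5.29 in nascent to 18.7 in 2 h DMSO chromatin, and to 7.34 in 2 h triptolide chromatin.

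Replication-dependent histone genes, transcribed in S phase, gained most of all lists, with a median of 1.52 ± 0.20 RPM in nascent and 10.6 ± 0.85 RPM in 2 h chromatin (SD, n = 3). Of 57 measured, 55 rose and none fell (57 and 0 adjusted over the list alone), with a median log2 difference of 2.16 against 0.48 for all 23623 genes (camera, Benjamini-Hochberg adjusted p = 4.2e-27). H2ac8 rose 3.02 log2 (SE 0.34, adjusted p = 6.2e-13) and H3c6 rose 2.98 (SE 0.33), but copies of histone genes are near-identical, so reads may be shared among them. Rnu3a, coding for the U3 small nucleolar RNA (3.29, from 3.26 ± 0.88 to 40.2 ± 3.06 RPM), and the U1 small nuclear RNA gene Rnu1a1 (2.93, SE 0.32) rose too, with the same doubt. Wdpcp rose 3.35 log2 (SE 0.29, adjusted p = 9.5e-19), from 2.60 ± 1.76 to 31.9 ± 3.06 RPM, and Mdh1, whose window overlaps it, 3.29. Mtmr4 rose 2.93 (SE 0.30). Of 34 pluripotency genes 23 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 0.0091, adjusted p = 0.072 with an estimated correlation). Among them Fbxo15 rose 2.2, Trim28 2.15, Zfp42 1.57, Nanog 1.5 (SE 0.31, from 3.24 ± 0.76 to 11.2 ± 3.76 RPM) and Sox2 1.11 (SE 0.30). Pou5f1 rose 0.98 (adjusted p = 0.0095), a call lost without 2 h DMSO replicate 3 (adjusted p = 0.078) or nascent DMSO replicate 1 (0.053). Klf4 did not pass (0.69, adjusted p = 0.13).

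Of 23 immediate early genes 13 rose (15 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.0059, adjusted p = 0.065 with an estimated correlation), among them Ccn2 at 2.31 (SE 0.30), Zfp36 at 1.90, Fos at 1.52 (SE 0.34) and Myc at 1.29 (SE 0.27). Of 20 p53 targets 11 rose (13 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.027, adjusted p = 0.16 with an estimated correlation), including Ccng1 at 1.62 and Polk at 1.61. Of 24 housekeeping genes 15 rose (18 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 0.011, adjusted p = 0.080 with an estimated correlation), including Nono at 2.13 and Vcp at 1.57. Of 81 ribosomal protein genes 36 rose (41 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.084), among them Rpl39 at 1.80. Of 66 Polycomb-bound regulators 28 rose (30 adjusted over the list alone), with a median of 0.65 and Hoxc13 at 1.65. The olfactory receptors stayed behind, with 4 of 951 higher and 24 lower (0 and 0 adjusted over the list alone) and a median of -0.07 (camera adjusted p = 2.8e-18, adjusted p = 4.3e-06 with an estimated correlation). Their median was 0.00 with libraries scaled to background. In the marker lists of other cell types 5 of 13 primitive endoderm genes rose (median 0.58, Lamb1 1.52, Sox17 1.49), 2 of 8 trophectoderm genes (median 0.77, Tead4 1.56), 3 of 11 fibroblast genes with 1 lower (median 0.35, Vim 2.06, Thy1 1.42), 4 of 12 neural and germ layer genes (median 0.60, Sox1 1.67, Fgf5 1.49) and 1 of 10 2-cell-like genes. Few genes fell, among them Zp1 at -1.45 and Cidec at -1.31, while Il1r2 and Lcn2 were listed at 0 at 2 h.

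limma called 9303 TSSs higher and 489 lower at 2 h of 29799 tested (median 0.34), and 5579 enhancers higher and 75 lower of 8774 (median 1.06). The enhancer window at chr2:134456001-134457000 rose 3.5 log2 (SE 0.32, adjusted p = 2.8e-19), from 0.54 ± 0.04 to 16.6 ± 3.31 RPM, and the window at chr8:4934001-4935000 rose 3.45. In the unbound fraction of the same samples limma called 0 of 30310 TSSs at 2 h against nascent, with 2177 at an unadjusted p under 0.05 and 0 by limma-voom. These splits depend on the scaling. Centred on each library's median TSS, 4742 TSSs were higher and 4186 lower, and 1585 enhancers higher and 1407 lower. Scaled to background windows, the median of all tested TSSs went from 0.34 to 0.71.

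The spike-in experiment repeats the 2 h and nascent comparison with S2 cells added, in 5 kb regions. What the deposited values were scaled to is not given in the sources used here, so levels are compared only as listed. limma called 9223 TSS regions higher and 414 lower of 30618 (median 0.79), and 5296 enhancer regions higher and 31 lower of 8788 (median 1.42). With the replicate number as a block, although the numbers showed no pairing, only 670 TSS regions were higher and 11 lower. Mean TSS signal was 4.53 ± 0.56 in nascent and 5.17 ± 0.10 in 2 h libraries (log2, SD, n = 2 each, exact permutation p = 0.33, the smallest that 2 against 2 can give). Histone genes led again, with 58 of 59 higher (59 adjusted over the list alone) and a median of 3.57 against 0.91 for all 24213 genes (camera adjusted p = 3.8e-62, adjusted p = 0.77 with an estimated correlation). H2ac24 and H4bc24, which share a region, rose 5.17 log2 (SE 0.64, adjusted p = 1.4e-12), and H2ac8 rose 4.94 (SE 0.52), from 10.5 ± 5.21 to 333 ± 5.56. Itgb8 rose 4.48 (SE 0.54), from 7.74 ± 4.51 to 181 ± 2.36.

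Of 34 pluripotency genes in the spike-in data 25 rose (26 adjusted over the list alone), with a median of 1.68 (camera adjusted p = 0.00038, lost with an estimated correlation, where every list had an adjusted p of 0.77 except the 2-cell-like one at 0.92), including Tdgf1 at 2.44, Zfp42 at 2.01, Sox2 at 1.77, Pou5f1 at 1.72 (SE 0.63) and Nanog at 1.38, while Klf4 (1.03, adjusted p = 0.13) and Esrrb (-0.48, adjusted p = 0.59) did not pass. Of 23 immediate early genes 17 rose (19 adjusted over the list alone, median 1.65, Ccn1 2.42, Fos 2.24, Myc 1.73, camera adjusted p = 0.00085, 0.77 estimated). Of 66 Polycomb-bound regulators 45 rose (55 adjusted over the list alone, median 1.45, Isl1 2.62, Irx3 2.10, camera adjusted p = 0.00014, 0.77 estimated). Of 81 ribosomal protein genes 37 rose (40 adjusted over the list alone, median 1.22, Rps12 2.62, camera adjusted p = 0.0083, 0.77 estimated), of 24 housekeeping genes 14 rose (19 adjusted over the list alone, median 1.38, Pgk1 2.13, camera adjusted p = 0.032, 0.77 estimated) and of 20 p53 targets 9 rose (12 adjusted over the list alone, median 1.27, Polk 2.54). Of 1010 olfactory receptors 18 rose and 13 fell (6 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 1.2e-16, 0.77 estimated). Marker genes of other cell types rose in 7 of 13 (primitive endoderm, Gata6 2.25), 3 of 8 (trophectoderm), 4 of 11 (fibroblast, Vim 2.67), 1 of 11 (2-cell-like) and 7 of 12 cases (neural and germ layer). Slc6a18 fell by 3.35 (SE 0.77). The counts depend on single libraries, and the nascent libraries differ more from each other than those of 2 h (mean TSS signal 4.13 and 4.92 against 5.24 and 5.10). Without 2 h replicate 1 limma called 3 TSS regions and 0 enhancer regions, without 2 h replicate 2 it called 2 and 0, without nascent replicate 1 it called 15285 TSS regions and without nascent replicate 2 18031. Centred on each library's median, 8228 TSS regions were higher and 6151 lower, 2026 enhancer regions higher and 1751 lower.

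Triptolide against DMSO in nascent chromatin asks whether blocking initiation alters accessibility just behind the fork. Ribosomal protein genes lost most of the lists, at a median of 1.01 ± 0.09 RPM with triptolide and 3.03 ± 0.15 with DMSO (SD, n = 3). Of 81, 37 fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -0.90 against -0.28 for all 23623 genes (camera adjusted p = 1.5e-10). Rpl35 fell by 1.83 (SE 0.31, adjusted p = 1.0e-05) and Rpl6 at -1.80 (SE 0.36). Housekeeping genes fell in 9 of 24 cases (11 adjusted over the list alone, median -0.68, camera adjusted p = 0.0064, adjusted p = 0.079 with an estimated correlation), including Hspa8, a heat shock chaperone, at -1.65 (SE 0.27) and Ncl, coding for nucleolin, at -1.60 (SE 0.28). The genes with the largest losses were Ywhab (-2.31, SE 0.30, from 6.53 ± 1.58 to 0.50 ± 0.17 RPM, adjusted p = 3.0e-08), the replication gene Gins4 (-2.30, SE 0.30), Fn3krp (-2.19), the nuclear receptor gene Nr2c2 (-2.19), Zfp322a (-2.18), Smim4 (-2.17) and Mcm6, a subunit of the replicative helicase (-2.1, SE 0.32). Tex19.1 was listed at 0 with triptolide and at 4.33 ± 2.12 RPM with DMSO.

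Of 34 pluripotency genes 4 fell and 1 rose (6 and 1 adjusted over the list alone, median -0.43, camera adjusted p = 0.82). Sox2 fell by 1.04 (adjusted p = 0.013), lost without triptolide replicate 3 (adjusted p = 0.077), and Mycn at -1.14, lost without triptolide replicate 1 (0.11) or DMSO replicate 2 (0.052). Nanog (-0.41, adjusted p = 0.43), Zfp42 (-0.76, adjusted p = 0.067) and Pou5f1 (0.03, adjusted p = 0.98) did not pass. Of 23 immediate early genes 3 fell (7 adjusted over the list alone, median -0.41), among them Srf at -1.37 (SE 0.30). Of 57 histone genes 11 fell (13 adjusted over the list alone, median -0.45, camera adjusted p = 0.24), H2bc7 at -1.48. Of 20 p53 targets 4 fell (6 adjusted over the list alone, median -0.24). Of 66 Polycomb-bound regulators 2 fell (1 adjusted over the list alone), Nkx6-1 at -1.62, and their median of -0.15 turned to 0.07 with centring. Of 951 olfactory receptors 7 rose and 5 fell (0 and 0 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 2.8e-11, adjusted p = 5.4e-05 with an estimated correlation). Primitive endoderm markers fell in 1 of 13 cases (Lama1 at -1.13, lost without triptolide replicate 2, adjusted p = 0.066). None of 8 trophectoderm (median -0.13), 11 fibroblast (-0.04), 10 2-cell-like (0.02) or 12 neural and germ layer markers (-0.28) passed. Among the few genes that rose were Omt2b by 1.35 (SE 0.38, adjusted p = 0.0091) and Treh by 1.14, and Gsdma2 was listed at 0 with DMSO.

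limma called 134 TSSs higher and 3446 lower with triptolide in nascent chromatin of 29799 (median -0.23), and 21 enhancers higher and 274 lower of 8774 (median -0.18). The enhancer window at chr4:45108001-45109000 fell by 1.83 (adjusted p = 0.00029), from 2.94 ± 0.08 to 0.12 ± 0.21 RPM, and the one at chr5:108035501-108036500 rose by 1.40. The ratio of TSS signal to background was 2.96 ± 0.15 with triptolide against 5.29 ± 0.10 (SD, n = 3 each, exact permutation p = 0.1), and at enhancers 2.86 ± 0.03 against 4.35 ± 0.15. Without triptolide replicate 2 the TSS count was 2199, and without triptolide replicates 1, 2 and 3 or DMSO replicates 1 and 2, each in turn, the enhancer count was 128, 136, 177, 182 and 133. Centred, 358 TSSs were higher and 1200 lower, 26 enhancers higher and 39 lower.

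DRB against DMSO in nascent chromatin asks the same of blocked elongation. The ratio of TSS signal to background was 3.39 ± 0.25 with DRB against 5.29 ± 0.10 (SD, n = 3 each, exact permutation p = 0.1), and at enhancers 3.03 ± 0.25 against 4.35 ± 0.15. Rbm42, coding for an RNA-binding protein, fell by 2.0 log2 (SE 0.33, adjusted p = 3.9e-05), from 5.46 ± 0.37 to 0.76 ± 0.94 RPM. Rnf5, a ubiquitin ligase gene, fell by 1.98, Mllt1, a gene of the super elongation complex, at -1.93, Tmem127 and Ciao1, which share a window, at -1.93, Smim4 at -1.92, Narf at -1.90 and the ribosomal protein gene Rplp1 at -1.90. Housekeeping genes fell in 4 of 24 cases (7 adjusted over the list alone, median -0.47, camera adjusted p = 0.019, adjusted p = 0.11 with an estimated correlation), among them Tfrc, the transferrin receptor gene, at -1.87 (SE 0.31). Ribosomal protein genes fell in 6 of 81 cases (10 adjusted over the list alone, median -0.34, camera adjusted p = 0.095). Of 34 pluripotency genes 2 fell (2 adjusted over the list alone, median -0.39, camera adjusted p = 0.053), Utf1 at -1.24 (lost without DRB replicate 2, adjusted p = 0.067, or DMSO replicate 3, 0.11) and Klf2 at -1.14 (lost without DRB replicate 2, adjusted p = 0.16, or DMSO replicate 2, 0.063). Sox2 (-0.83, adjusted p = 0.098), Nanog (-0.46, adjusted p = 0.41) and Pou5f1 (-0.33, adjusted p = 0.60) did not pass.

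Of 23 immediate early genes 1 fell with DRB (4 adjusted over the list alone, median -0.23), and of 57 histone genes 1 fell (1 adjusted over the list alone, median -0.05, which turned to 0.10 with centring). None of 20 p53 targets (median -0.05, 0.09 with centring), 66 Polycomb-bound regulators (median -0.31), 13 primitive endoderm (-0.21), 8 trophectoderm (-0.08) or 12 neural and germ layer markers (-0.33) passed. Of 951 olfactory receptors 11 rose and 2 fell (0 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 1.9e-10, adjusted p = 8.1e-05 with an estimated correlation). Fibroblast markers had a median of 0.03, which turned to -0.05 with background scaling (camera adjusted p = 0.035, adjusted p = 0.11 with an estimated correlation), and 1 of 11 rose, Col3a1, a call lost without any single DMSO library (adjusted p = 0.12, 0.13 and 0.061) or without DRB replicate 1 or 2 (0.055 and 0.12). The 2-cell-like markers had a median of 0.12 with none of 10 called (camera adjusted p = 0.039, adjusted p = 0.18 with an estimated correlation). Speer2 rose by 1.34 (SE 0.32, adjusted p = 0.0084), lost without DMSO replicate 1 (0.056), and Olfr1045 and Cypt4 were listed at 0 with DMSO. limma called 84 TSSs higher and 1003 lower (median -0.18), and 13 enhancers higher and 119 lower (median -0.15), including the window at chr13:112440001-112441000 at -1.71 (adjusted p = 0.0011). limma-voom called 91 TSSs and 2 enhancers. Without DMSO replicate 1, 2 or 3 the TSS count was 658, 573 or 649, and without DMSO replicate 1 or 2 the enhancer count was 76 or 33. Centred, 117 TSSs were higher and 289 lower, 14 enhancers higher and 35 lower.

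Triptolide against DMSO at 2 h asks whether the return of accessibility needs initiation. The ratio of TSS signal to background was 7.34 ± 0.34 with triptolide and 18.7 ± 2.05 with DMSO (SD, n = 3 each, exact permutation p = 0.1), 0.39-fold, and at enhancers 9.03 ± 0.81 and 24.5 ± 3.59, 0.37-fold. Histone genes were at a median of 1.63 ± 0.35 RPM with triptolide and 10.6 ± 0.85 with DMSO, and 54 of 57 fell (54 adjusted over the list alone), with a median of -2.04 against -0.40 for all genes (camera adjusted p = 1.2e-22). H2bc15 and H2ac15, which share a window, fell by 3.14 (SE 0.33, adjusted p = 2.9e-14), from 18.6 ± 0.22 to 1.26 ± 0.46 RPM. Rnu3a fell by 3.97 (SE 0.30, adjusted p = 1.6e-23), from 40.2 ± 3.06 to 1.63 ± 0.21 RPM, Rnu3b4 at -3.55, Rnu1a1 at -3.16 and Rnu3b1 at -2.97, near-identical copies that may share reads. The window of Rnu3a (chr10:40258001-40259000) is also in the enhancer set. Msh4, a meiotic MutS homologue, fell by 3.18 (SE 0.33) and Mroh1 at -3.07 (SE 0.32). Ribosomal protein genes were at 2.2 ± 0.09 RPM against 5.32 ± 0.86, and 51 of 81 fell and 1 rose (55 and 1 adjusted over the list alone, median -1.11, camera adjusted p = 1.5e-05), while Rpl10 was listed at 0 with triptolide. Housekeeping genes fell in 16 of 24 cases (20 adjusted over the list alone, median -1.13, camera adjusted p = 0.0025), Vcp at -1.78 and Pgk1 at -1.69.

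**Figure D3:**
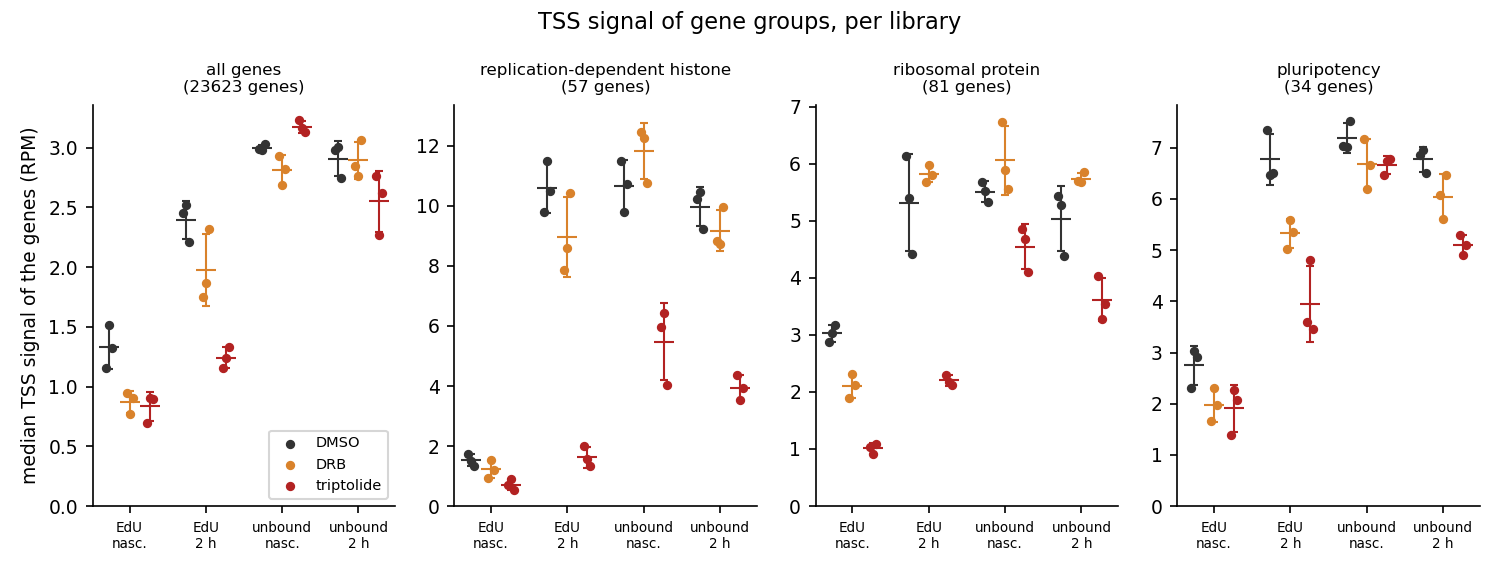
Median TSS RPM of all genes, histone, ribosomal protein and pluripotency genes in each EdU and each unbound library (points) with the mean and SD of each group (n = 3). In the EdU libraries histone genes go from 1.52 RPM in nascent to 10.6 in 2 h DMSO chromatin, and stand at 1.63 in 2 h triptolide chromatin.

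Of 34 pluripotency genes 15 fell (15 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.76). Trim28 fell by 2.08 (SE 0.29), Utf1 at -1.80, Zfp42 at -1.27 (SE 0.29, from 16 ± 2.4 to 6.04 ± 0.81 RPM) and Sox2 at -1.0 (SE 0.30), while Pou5f1 fell by 0.78 (adjusted p = 0.045, lost without triptolide replicate 1, 0.44, or 3, 0.064, or DMSO replicate 2, 0.081, or 3, 0.21). Nanog (-0.66, adjusted p = 0.094) did not pass. Of 23 immediate early genes 10 fell (12 adjusted over the list alone, median -0.81), among them Srf at -1.70 and Klf6 at -1.61, while Myc (-0.40, adjusted p = 0.29) and Fos (-0.73, adjusted p = 0.088) did not pass. Of 20 p53 targets 6 fell (6 adjusted over the list alone, median -0.38), Polk at -1.81 and Sesn1 at -1.46. Of 66 Polycomb-bound regulators 11 fell (7 adjusted over the list alone, median -0.33, which turned to 0.03 with centring), Six2 at -1.64 and Olig1 at -1.5. Of 12 neural and germ layer markers 7 fell (7 adjusted over the list alone, median -0.81, Pou3f1 -1.35), of 13 primitive endoderm markers 4 (5 adjusted over the list alone, median -0.50, Lamb1 -1.51), of 8 trophectoderm markers 1 (Tead4, -1.19, median -0.41) and of 11 fibroblast markers 1 (Vim, -0.84). Vim lost its call without triptolide replicate 2 (adjusted p = 0.0503) or 3 (0.075) or DMSO replicate 2 (0.086) or 3 (0.054). No 2-cell-like marker passed (median -0.06). Of 951 olfactory receptors 5 rose and 3 fell (1 and 0 adjusted over the list alone), with a median of 0.00 (camera adjusted p = 1.0e-12, adjusted p = 3.3e-05 with an estimated correlation).

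Genes that rose with triptolide at 2 h were at low levels with DMSO. Fblim1, coding for a filamin-binding adhesion protein, rose 2.37 (SE 0.38, adjusted p = 1.5e-07), from 0.21 ± 0.19 to 5.27 ± 0.83 RPM, Tarm1 1.92, Sema4a 1.88, Apoc4 1.86, Igll1 1.86, Prss16 1.86, Hpgds 1.86 and Olfr221 1.71. limma called 812 TSSs higher and 8516 lower (median -0.29). The TSSs called higher lay in a steady-state peak in 32.8% of cases and carried S5P in 2.96%, against 98.9% and 43.9% of those called lower and 46.4% and 10.4% of the 20471 not called. Their median DMSO level was 0.41 RPM, against 7.26 if called lower and 0.59 if not called, partly set by the calling. In the unbound fraction 196 of the 812 were called higher and 2 lower. limma called 221 enhancers higher and 4174 lower (median -0.72), with the window at chr9:15317001-15318000 at -3.32 (SE 0.36, from 15.1 ± 1.26 to 0.69 ± 0.61 RPM) and the one at chr4:142167501-142168500 at 2.00. Centred on each library's median, 2449 TSSs were higher and 4627 lower, and 1169 enhancers higher and 959 lower. Scaled to background windows, the median of all TSSs went from -0.29 to -0.48.

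DRB against DMSO at 2 h asks the same of elongation. p53 targets, genes of the stress and DNA damage response, were higher as a group, with a median of 0.52 (camera adjusted p = 3.0e-08, adjusted p = 0.0034 with an estimated correlation) and 1 of 20 called (3 adjusted over the list alone). The called gene was Sesn2, which rose 1.13 (adjusted p = 0.034, lost without DRB replicate 1, 0.085, 2, 0.11, or 3, 0.12, or DMSO replicate 2, 0.42), while Plk2 did not pass (0.97, adjusted p = 0.097). Of 23 immediate early genes 2 rose (3 adjusted over the list alone), with a median of 0.06 that turned to -0.09 with background scaling (camera adjusted p = 0.014, adjusted p = 0.087 with an estimated correlation). These were Junb, an AP-1 factor, at 1.49 (SE 0.31, adjusted p = 0.0031, from 4.45 ± 1.15 to 14.1 ± 0.66 RPM) and the antiproliferative gene Btg2 at 1.39 (lost without DRB replicate 1, adjusted p = 0.14, or DMSO replicate 1, 0.052, or 3, 0.099). Of 81 ribosomal protein genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.08 that turned to -0.06 with background scaling (camera adjusted p = 5.0e-05, adjusted p = 0.012 with an estimated correlation). Rpl4 rose 1.57 (lost without DRB replicate 2, adjusted p = 0.059, or DMSO replicate 2, 0.18), and Rpl13a 1.34 (lost without DRB replicate 1, adjusted p = 0.073, or 2, 0.25, or DMSO replicate 2, 0.38, or 3, 0.051). Histone genes were at 8.96 ± 1.33 RPM against 10.6 ± 0.85, with none of 57 called (6 lower adjusted over the list alone, median -0.10, which turned to 0.04 with centring).

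None of 34 pluripotency genes passed with DRB at 2 h (median -0.31). Pou5f1 (-0.53, adjusted p = 0.51), Nanog (-0.28, adjusted p = 0.80) and Sox2 (-0.0092, adjusted p = 1.0) were among them. No housekeeping gene passed (2 lower adjusted over the list alone, median -0.10, which turned to 0.04 with centring). No Polycomb-bound regulator passed either, with a median of 0.01 that turned to -0.12 with background scaling (camera adjusted p = 0.030, adjusted p = 0.44 with an estimated correlation). No olfactory receptor passed (median 0.0048, camera adjusted p = 1.7e-05, adjusted p = 0.0025 with an estimated correlation), nor did any marker of primitive endoderm (median -0.23), trophectoderm (-0.10), fibroblasts (0.17), the 2-cell-like state (-0.04) or neural and germ layers (-0.28). Gramd2 fell by 2.66 (SE 0.32, adjusted p = 3.5e-10), from 24.8 ± 4.82 to 3.10 ± 0.82 RPM, and Msh4 at -2.09 (SE 0.33). Traf2, an adaptor of TNF receptors, fell by 1.79, Dnajb14 at -1.76 and Cd68 at -1.73. Ankrd65 rose 1.83 (SE 0.37), the interferon gene Ifna13 1.76, Agtr1b 1.59 and Tcrb 1.54, and Cbfa2t3 was listed at 0 with DMSO. limma called 60 TSSs higher and 185 lower (median -0.12), and 42 enhancers higher and 400 lower (median -0.24), including the window at chr9:15317001-15318000 at -2.90 (SE 0.36) and the one at chr2:167065501-167066500 at -2.85. The ratio of TSS signal to background was 13.6 ± 1.43 against 18.7 ± 2.05 (SD, n = 3 each, exact permutation p = 0.1), and at enhancers 17.4 ± 0.65 against 24.5 ± 3.59. The size of these counts depends on settings and single libraries. Scaled to background windows 175 TSSs were higher and 1517 lower, centred 74 higher and 54 lower, with 107 enhancers higher and 38 lower, and with a pseudocount of 0.25 20 TSSs and 3 enhancers were called. Without DRB replicate 1 or 2 or DMSO replicate 1, 2 or 3 the TSS count was 74, 97, 68, 50 or 72. Without DRB replicate 1, 2 or 3 the enhancer count was 183, 219 or 189, and without DMSO replicate 1, 2 or 3 it was 124, 93 or 236.

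**Figure D4:**
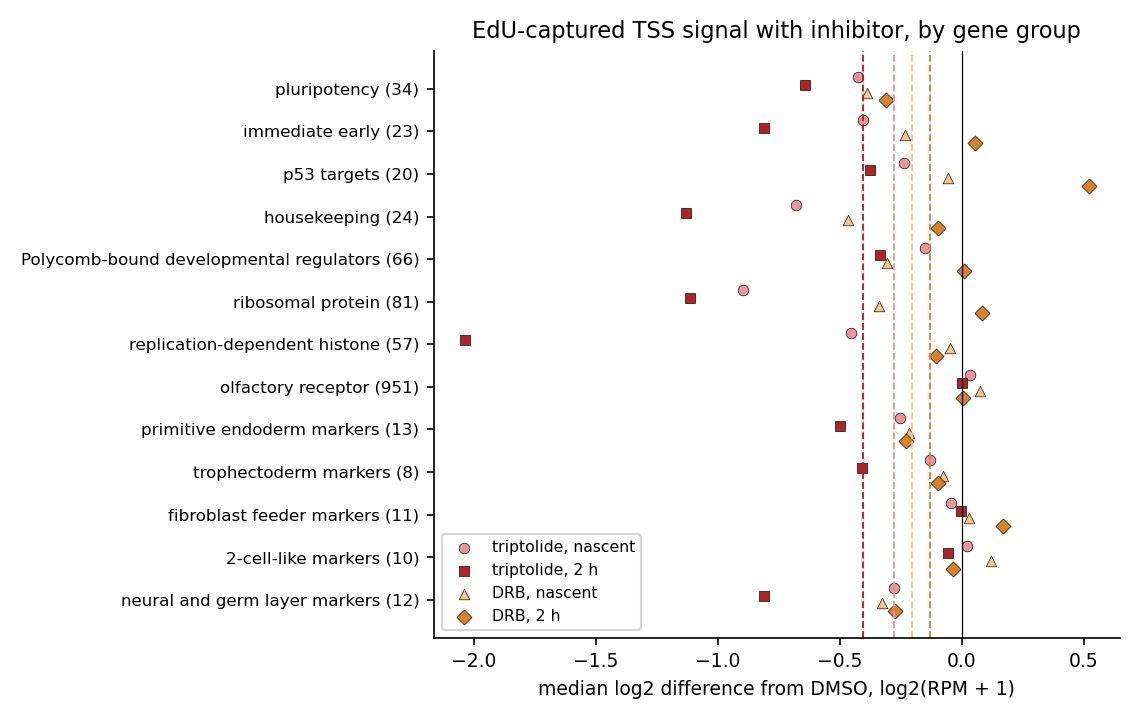
Median log2 difference from DMSO of each gene list in EdU-captured chromatin, for triptolide and DRB in nascent and 2 h chromatin; dashed lines are the medians of all genes. Histone genes are at -2.04 with triptolide at 2 h, and p53 targets at 0.52 with DRB at 2 h.

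The unbound fraction shows what the inhibitors do to chromatin that was for the most part not labelled. Histone genes fell there too. Their median was 5.48 ± 1.27 RPM with triptolide against 10.7 ± 0.87 in the nascent samples (45 of 57 lower, 53 adjusted over the list alone, median -0.80, camera adjusted p = 1.4e-55, adjusted p = 0.0049 with an estimated correlation), and 3.95 ± 0.42 against 9.98 ± 0.64 at 2 h (53 of 57 lower, 54 adjusted over the list alone, median -1.05, camera adjusted p = 2.7e-40). Ribosomal protein genes fell with triptolide in 11 of 81 cases in the nascent samples (21 adjusted over the list alone, median -0.25, camera adjusted p = 7.0e-12, adjusted p = 0.10 with an estimated correlation). At 2 h 24 fell and 1 rose (36 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 6.9e-06, adjusted p = 0.20 with an estimated correlation). Of 34 pluripotency genes 12 fell and 1 rose at 2 h (16 and 1 adjusted over the list alone, median -0.35, camera adjusted p = 0.0093, adjusted p = 0.17 with an estimated correlation), and of 24 housekeeping genes 10 fell (13 adjusted over the list alone, median -0.44, camera adjusted p = 6.9e-06, adjusted p = 0.037 with an estimated correlation). p53 targets were higher with DRB, at a median of 0.29 in the nascent samples (1 of 20 called, 7 adjusted over the list alone, camera adjusted p = 5.5e-06, adjusted p = 0.064 with an estimated correlation) and 0.41 at 2 h (2 called, 9 adjusted over the list alone, camera adjusted p = 2.6e-10, adjusted p = 0.017 with an estimated correlation). Of 30310 TSSs limma called 215 higher and 463 lower with triptolide in the nascent samples and 686 higher and 3711 lower at 2 h, and with DRB 81 higher and 193 lower and, at 2 h, 233 higher and 216 lower. Enhancer ratios to background were 28.4 with DMSO, 24.6 with DRB and 21.8 with triptolide in the nascent samples, and 27.7, 21.2 and 13.9 at 2 h. TSS ratios were 23.1, 19.8 and 21.2 in the nascent samples and 21.0, 19.3 and 14.1 at 2 h, and overlapped DMSO for nascent triptolide (exact permutation p = 0.2) and 2 h DRB (p = 0.4). Centred, the nascent triptolide split was 150 higher and 806 lower, and the 2 h DRB split 193 higher and 292 lower. Scaled to background, the splits were 111 and 517 (nascent triptolide), 60 and 375 (nascent DRB), 394 and 7590 (2 h triptolide) and 117 and 294 (2 h DRB).

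Unbound counts also rested on single libraries. The nascent triptolide count was 374 without triptolide replicate 2, 328 without triptolide replicate 3 and 407 without DMSO replicate 2. The nascent DRB count was 172, 106 and 84 without DRB replicates 1, 2 and 3 in turn and 112 without DMSO replicate 2. The 2 h triptolide count was 2910 without DMSO replicate 2. The 2 h DRB count was 289, 263 and 287 without DRB replicates 1, 2 and 3 in turn, and 289, 212 and 237 without DMSO replicates 1, 2 and 3.

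The drug effect in the EdU minus that in the unbound fraction asks what is particular to replicated chromatin. Histone genes had a positive difference for triptolide in nascent chromatin (median 0.39, 3 of 57 higher, 3 adjusted over the list alone, camera adjusted p = 3.2e-12, adjusted p = 0.0086 with an estimated correlation). With limma-voom their median was 0.04, so the difference belongs to the log2(RPM + 1) scale, where low levels move less. In RPM they went from 1.52 to 0.71 in the EdU and from 10.7 to 5.48 in the unbound fraction. At 2 h 24 of 57 had a larger loss in the EdU fraction (30 adjusted over the list alone, median -0.91, camera adjusted p = 6.9e-06, adjusted p = 0.15 with an estimated correlation). Ribosomal protein genes had a larger loss in the EdU fraction in 12 of 81 cases in nascent chromatin (19 and 1 of the other sign adjusted over the list alone, median -0.55, camera adjusted p = 0.010, adjusted p = 0.22 with an estimated correlation). At 2 h this held for 22 of 81, with 1 of the other sign (26 and 1 adjusted over the list alone, median -0.67, camera adjusted p = 0.014, adjusted p = 0.25 with an estimated correlation). With DRB in nascent chromatin 2 of 24 housekeeping genes had a larger loss (6 adjusted over the list alone, median -0.46, camera adjusted p = 0.0069, adjusted p = 0.079 with an estimated correlation). Of 30469 TSSs limma called 101 with a positive and 2159 with a negative difference for triptolide in nascent chromatin, 111 and 3848 at 2 h, and 14 and 121 for DRB in nascent chromatin. For DRB at 2 h limma called 0, with 2311 at an unadjusted p under 0.05 and 0 by limma-voom. Centred, the nascent splits were 298 and 396 for triptolide and 15 and 19 for DRB.

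Single libraries moved these counts. The nascent triptolide count was 1232 and 1496 without unbound triptolide replicates 1 and 2. It was 1457 and 1494 without unbound DMSO replicates 2 and 3. At 2 h it was 2626 without unbound triptolide replicate 1 and 2572 without unbound DMSO replicate 3. For DRB in nascent chromatin it was 339, 287 and 836 without EdU DRB replicates 1, 2 and 3, 278 without EdU DMSO replicate 3, 6, 22 and 32 without unbound DRB replicates 1, 2 and 3, and 69, 15 and 27 without unbound DMSO replicates 1, 2 and 3. For DRB at 2 h it was 2 without EdU DRB replicate 3.

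Whether a drug effect is larger in 2 h than in nascent samples was tested as the difference of its effects. The 2 h samples were also taken 2 h later after the start of the drug. Age of the chromatin and time since that start can thus not be told apart. In the unbound fraction the TSS ratio to background with triptolide was 0.92-fold that of DMSO in the nascent samples and 0.67-fold at 2 h. For triptolide limma called 9 TSSs with a positive and 125 with a negative difference of 29799, and 22 of 57 histone genes among them, all negative (47 adjusted over the list alone, median -1.58 against -0.17 for all genes, camera adjusted p = 2.0e-37, adjusted p = 7.4e-06 with an estimated correlation). The olfactory receptors had a median of -0.02, which turned to 0.11 with centring (camera adjusted p = 0.023, adjusted p = 0.043 with an estimated correlation). Chosen after their values were seen, the largest negative differences included the U1 gene Rnu1a1 (-3.08, SE 0.46, adjusted p = 3.2e-06), the U3 gene Rnu3a (-2.77) and H2bc18 (-2.76, adjusted p = 0.0002), and the positive ones the imprinting factor gene Zfp57 (2.46, SE 0.51, adjusted p = 0.0027), Tbxa2r (2.23) and Igll1 (2.21). For DRB limma called 6 TSSs. Named after their values were seen, these were Cbfa2t3 (2.45, adjusted p = 0.019), Rack1 (2.1), Junb (2.04), an unnamed TSS in chr16:11143501-11144500 (1.87), the microRNA gene Mir295 (-2.12) and Lrrc75a (-2.65, adjusted p = 0.0021). Ribosomal protein genes had a positive difference for DRB, with a median of 0.45 and none called (7 higher adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.0098 with an estimated correlation).

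The triptolide count was 83 without 2 h triptolide replicate 2 or 3, and 51, 49 and 59 without 2 h DMSO replicates 1, 2 and 3. limma-voom called 20, a pseudocount of 0.25 13 and centring 57, while scaling to background gave 893 and a fit of only the groups compared 313. The DRB count was 2, 3 and 1 without 2 h DRB replicates 1, 2 and 3, 3 and 0 without 2 h DMSO replicates 2 and 3, 3 without nascent DRB replicate 1, and 1 and 2 without nascent DMSO replicates 1 and 3. Scaled to background it was 9 positive and 2 negative.

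Steady-state peaks were also grouped by the first list of the time series that held them. Peaks already in the nascent list (34251) stood at -0.36 with triptolide and -0.34 with DRB in nascent chromatin, and at -0.52 and -0.17 at 2 h (mean log2, n = 3 against 3). Peaks held only by the steady-state list (53582) stood at -0.06, -0.09, -0.10 and -0.05. The difference between these groups of peaks was -0.30, -0.24, -0.42 and -0.12 (exact permutation test of each, two-sided, p = 0.1, the smallest possible). The classes between lay closer to the nascent one at 2 h. With triptolide, peaks first held by the 30 min, 1 h and 2 h lists stood at -0.46, -0.46 and -0.40, and the difference of the nascent class from the 2 h class was -0.13 with triptolide (exact permutation p = 0.1) and -0.033 with DRB (p = 0.5). Enhancer peaks of the nascent list were at -0.99 with triptolide at 2 h and those of the steady-state list only at -0.40. TSSs in steady-state peaks with S5P (5871) were at -1.03 with triptolide at 2 h, and those without S5P (12331) at -0.62, a difference of -0.41 (exact permutation p = 0.1). For DRB at 2 h that difference was -0.06. The unbound fraction showed the same order with triptolide at 2 h, with means from 2.91 to 2.61 for TSSs with S5P and from 2.29 to 2.15 for those without, and from 2.62 to 2.34 for peaks of the nascent list and from 1.18 to 1.11 for those of the steady-state list only, so the order is not particular to the EdU fraction. TSSs with S5P had gained 0.98 from nascent to 2 h in DMSO, and those without 0.76. Peaks with higher signal have more room to fall in log2(RPM + 1), and peak height was not matched between the groups.

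**Figure D5:**
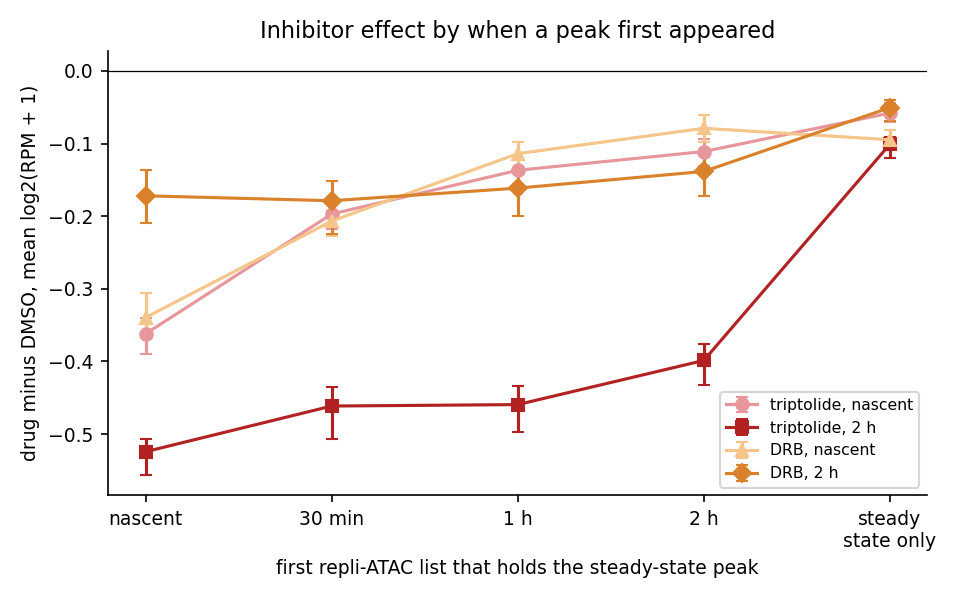
Mean log2 difference between drug and DMSO in EdU-captured chromatin for steady-state peaks grouped by the first list of the time series that holds them; bars span the values when each library is left out in turn. Peaks of the nascent list stand at -0.52 with triptolide at 2 h and peaks of the steady-state list only at -0.10.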

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

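Chosen only after the result was seen were the test of a scaling factor, the use of the unbound libraries as a test of tagmentation, the test of background scaling for TSSs higher with triptolide, and all counts from limma-voom or ratios to background.

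Drug effects that differed between nascent and 2 h chromatin, or between fractions, were picked up by limma or camera tests of the difference. For triptolide 134 TSSs differed between 2 h and nascent chromatin, and for DRB 6. Between EdU and unbound fractions 2260 differed for nascent triptolide, 3959 at 2 h and 135 for nascent DRB. Each count shrank under some settings below, the 135 to nearly none with limma-voom. Of 100 splits of the libraries drawn at random, 9 gave at least 134 calls (highest other 6170), 10 at least 6 (highest other 290), 5 at least 2260 (highest other 3437), 9 at least 3959 (highest other 9615) and 8 at least 135 (highest other 1328), so over all splits drawn chance is not excluded. For 2 h DRB between fractions limma called 0 TSSs, and all 100 splits gave as many (highest other 189). Splits with many more calls than the real one point to a structure of the samples. Those that swap drug and DMSO libraries in only one arm turn the difference of drug effects into their sum, so they are a poor reference. Among the 44 splits without such a swap, 4, 2, 2, 4 and 3 gave as many calls in the same order, with the highest others at 1175, 6, 2549, 7310 and 433. That share is under 0.05 for the 6 and the 2260 calls and not for the others, in a subset of splits picked after the result was seen.

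The same tests picked out 3 gene lists, with an estimated correlation as well. Histone genes had a median difference of -1.58 between the triptolide effects at 2 h and in nascent chromatin, and of 0.39 between EdU and unbound fractions in nascent chromatin, the latter only on the log2(RPM + 1) scale, since limma-voom gave 0.04. Ribosomal protein genes had 0.45 between the DRB effects at 2 h and in nascent chromatin. Olfactory receptor genes had -0.021 for triptolide, 2 h against nascent. Between fractions they had 0.016 (nascent triptolide), 0.024 (nascent DRB), -0.028 (2 h triptolide) and -0.0065 (2 h DRB). Those small medians stand apart because camera compares a list with all other genes, which fell, and silent genes near 0 RPM have little room to fall. How many splits would give lists as extreme was not tested.

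For the comparisons of 3 with 3 libraries the 10 possible splits are too few for a share under 0.05. The real split gave 3580 TSSs for nascent triptolide (highest other 2), 1087 for nascent DRB (2), 9328 for 2 h triptolide (0), 245 for 2 h DRB (0) and 9792 for 2 h against nascent DMSO (0). In the unbound fraction these were 678, 274, 4397 and 449 for the drugs in that order, with highest others of 0, and 1 split of 10 gave as many in each. For 2 h against nascent in the unbound fraction limma called 0 TSSs, and 10 of 10 splits gave 0, with 2177 TSSs at an unadjusted p under 0.05 and 0 by limma-voom. At enhancers the counts were 295 (highest other 0), 132 (9), 4395 (0), 442 (0) and 5654 (0).

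TSS signal rose from nascent to 2 h DMSO chromatin. A factor that multiplies all windows of a library alike leaves the ratio of TSSs to background as it is, yet the lowest 2 h ratio was 3.06 times the highest nascent one, which argues against it. With all libraries thinned to 1.30 M reads, 5326 TSSs were higher and 140 lower, against depth as the cause. Mean TSS signal differed by -0.030 in the unbound and 0.45 in the EdU libraries of the same samples, against a tagmentation that differed between cultures. EdU background fell from 0.30 to 0.19 RPM and TSSs rose from 1.60 to 3.60, so both raised the ratio. Whether the fall alone lifted TSS RPM was not tested. A return of accessibility is left as a hypothesis.

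Histone genes rose most to 2 h and fell most of the lists with triptolide at 2 h. Neighbouring genes that share a window do not make the count, since 49 of 53 distinct windows were called in both comparisons. Windows outside peaks around these genes had a median of -0.37 at 2 h, where the TSSs had 2.16, and of -0.15 with triptolide, where the TSSs had -2.04. All flanks were at -0.77 and 0.31, so the histone flanks stood above them at 2 h and below them with triptolide. A change in the captured amount of the clusters in the direction of the TSS changes is thus not excluded. The flanks moved far less than the TSSs, which argues against it as the whole cause. Thinned, 51 of 57 histone genes were still higher at 2 h and 47 lower with triptolide, against depth. Opening of these promoters with their transcription in S phase may explain both changes, as a hypothesis, whereas a shift of the cells out of S phase under triptolide was not tested.

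Triptolide at 2 h went with 812 TSSs higher. Fewer reads in peaks lift all other windows in RPM, but with libraries scaled to background 750 of the 812 were still called higher, which argues against that as the whole cause. limma-voom, which weighs the noise of windows with few reads, called 804 of the 812 higher. It used the same reads that picked these TSSs, so it cannot tell such noise from a change. The unbound libraries, where 196 were higher and 2 lower, argue against noise for those 196. After thinning, which weakens calls in both directions, only 330 TSSs were higher and 5097 lower. Of the 812, 32.8% lay in a steady-state peak (46.4% if not called). Their DMSO median, 0.41 RPM (0.59 if not called), is partly set by selection. Access to sites closed without the drug could be the reason, as a hypothesis, not separated here from DNA of dying cells.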

How the results depend on the processing

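Of the tests in this part, limma-voom and the ratio to background were chosen only after the result was seen. In the EdU fraction of the inhibitor experiment 3 of the large counts kept their direction and stayed within 1.5 times their count when single libraries were left out, namely 9328 TSSs for 2 h triptolide (7330 to 8057), 9792 TSSs for 2 h against nascent (7690 to 8863) and 5654 enhancers for 2 h against nascent (5133 to 5376). Over the other alternatives they were 6973 to 12633, 7649 to 14504 and 2992 to 6790. In the unbound fraction limma called 0 TSSs between 2 h and nascent under all 9 alternatives and all 6 libraries left out. Of 205 counts of calls under alternatives other than leaving out a library, 148 stayed within 1.5 times with the same direction, 20 grew, 32 shrank and 5 reversed. Of 2601 tests of named genes 2372 kept their call and none reversed, and of 442 tests of gene lists 400 kept theirs, with 42 weaker. With a library left out, 98 of 170 counts of calls stayed, 7 grew, 60 shrank and 5 reversed, and of 1757 tests of named genes 224 weakened and 27 strengthened. Of 63 peak or history values 37 moved and 2 weakened under other alternatives. All 120 ratios to background and 188 class means kept their value within their SD when a library was left out. For class means this was fixed in advance, and nearly so for ratios. Leaving out 1 of 3 or of 2 libraries moves a group mean by less than its SD, so it shows no stability. At the levels and depths of the nascent libraries 4% of simulated 0.5-fold changes were recovered, and 28% at those of 2 h, so counts of small changes are low. Depth is unknown for the peak lists. Except where the construction of an alternative is named, the cause of a change was not tested.

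Centring on the median TSS or enhancer sets that median to 0, so it removes a common loss or gain by construction. It gave 1558 TSSs for nascent triptolide, 406 for nascent DRB, 128 for 2 h DRB (74 higher and 54 lower, reversed from 60 and 185) and 57 for the difference of triptolide effects, 2 h against nascent. At enhancers it gave 65 for nascent triptolide, 49 for nascent DRB, 2128 for 2 h triptolide (1169 higher and 959 lower, reversed from 221 and 4174), 145 for 2 h DRB (107 and 38, reversed from 42 and 400) and 2992 for 2 h against nascent. Between EdU and unbound fractions it gave 694 (nascent triptolide), 34 (nascent DRB) and 1708 (2 h triptolide), and in the unbound fraction 485 for 2 h DRB (193 and 292, reversed from 233 and 216).

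Scaling to background gave 1692 TSSs and 1397 enhancers for 2 h DRB, 893 and 11 TSSs for the differences of triptolide and of DRB effects, and 435 (nascent DRB), 7984 (2 h triptolide) and 411 (2 h DRB, 117 and 294, reversed) in the unbound fraction. Between fractions it gave 1291 and 24 for nascent triptolide and DRB. Class means minus background moved by more than their SD for nascent triptolide (-0.23) and DRB (-0.19) at enhancers, 2 h triptolide at TSSs (-0.46), 2 h against nascent at TSSs (0.55) and enhancers (1.12) and nascent triptolide at unbound TSSs (-0.0054 from 0.01).

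Fitting only the groups compared, with fewer libraries to estimate the spread, gave 161 TSSs for nascent DRB, 1850 for 2 h DRB, 313 for the difference of triptolide effects, 830 for unbound 2 h DRB, 0 and 29 between fractions for nascent and 2 h DRB, and 150, 1 and 1124 enhancers for nascent triptolide, nascent DRB and 2 h DRB. limma-voom gave 91 and 1153 TSSs for nascent and 2 h DRB, 20 and 1 for the differences of triptolide and DRB effects, 413 and 846 for unbound nascent and 2 h DRB, 2 between fractions for nascent DRB, and 147, 2 and 729 enhancers for nascent triptolide, nascent DRB and 2 h DRB. A pseudocount of 0.25 gave 20 TSSs and 3 enhancers for 2 h DRB, 13 and 0 for the differences of triptolide and DRB effects and 2480 between fractions for 2 h triptolide. Without a filter these differences numbered 78 and 3. With a mean of at least 1 RPM, which tests fewer TSSs, they numbered 215 and 3, unbound nascent DRB 558 and nascent DRB between fractions 222. Windows within 1 kb gave 474 for 2 h DRB and 3 for the difference of DRB effects. The replicate block gave 414 for unbound nascent DRB and 681 TSS regions (670 higher and 11 lower) for the spike-in. Replicate numbers were not taken as pairs in the main fits, although a weak pairing is not excluded. EdU and unbound libraries of one number should share a capture, and pairing them, unlike the main fit, gave 56 for nascent DRB.

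Leaving out one library in turn gave, for TSSs, 2199 to 2945 (nascent triptolide), 573 to 1418 (nascent DRB), 50 to 209 (2 h DRB), 49 to 172 (difference of triptolide effects) and 0 to 8 (difference of DRB effects, with more negative than positive calls at 3 without 2 h DRB replicate 2, at 1 without 2 h DRB replicate 3 and at 1 without nascent DMSO replicate 1). In the unbound fraction it gave 328 to 708, 84 to 303, 2910 to 4420 and 212 to 289 for nascent triptolide, nascent DRB, 2 h triptolide and 2 h DRB. The last split reversed to 109 higher and 178 lower without DRB replicate 3, and to 115 and 122 without DMSO replicate 3. At enhancers the ranges were 128 to 206, 33 to 196 and 93 to 236 for nascent triptolide, nascent DRB and 2 h DRB, and between fractions 1232 to 2585, 6 to 836, 2572 to 3749 and 0 to 2 for nascent triptolide, nascent DRB, 2 h triptolide and 2 h DRB. The spike-in gave 2 to 18031 TSS and 0 to 7340 enhancer regions, where a lone library is assumed to vary like the other group in the pooled spread of limma.

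Camera with an estimated correlation called 1 list for nascent DRB, 3 for 2 h DRB, 2 for 2 h against nascent and 1 for the difference of DRB effects. For unbound chromatin it called 1, 0, 3 and 1 for nascent triptolide, nascent DRB, 2 h triptolide and 2 h DRB and 0 for 2 h against nascent, between fractions 2, 1 and 1 for nascent triptolide, nascent DRB and 2 h triptolide, and 0 for the spike-in. Where 0.5 of each peak had to overlap, 14.4%, 30.7%, 40.1% and 53.1% of steady-state peaks were in the nascent, 30 min, 1 h and 2 h lists, and of the peaks wider than the median 33.9%, 55.5%, 65.8% and 75.4%. The odds ratio of enhancer against other peaks was then 1.05 and 1.02 (Fisher's exact p = 0.18 and 0.50). A wider peak offers more bases to overlap.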

Other observations

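No test in this part was chosen only after the result was seen.

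Of the 34251 steady-state peaks in the nascent list, 4557 (13.3%) were not in the 2 h list, and 25138 steady-state peaks were in all 4 lists of replicated chromatin. Of the peaks of the nascent list 77.9% overlapped the steady-state list, as did 90.6% of the 30 min peaks, 93.0% of the 1 h peaks, 92.8% of the 2 h peaks and 90.9% of the 9632 S5P peaks. Of 18916 coding genes 49.3% had a TSS peak in the nascent list, 57.4% at 30 min, 61.4% at 1 h, 67.2% at 2 h and 72.7% at steady state, and of enhancers 21.0%, 50.6%, 63.0%, 70.5% and 83.1%.

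Mean enhancer signal in the unbound fraction differed from DMSO by -0.20 with triptolide in the nascent samples and by -0.46 at 2 h, and by -0.20 with DRB at 2 h (log2, n = 3 against 3, exact permutation p = 0.1, the smallest possible), and by -0.046 with DRB in the nascent samples (p = 0.2). At unbound TSSs the differences were 0.011 (nascent triptolide, exact permutation p = 0.4), -0.035 (nascent DRB, p = 0.2), -0.096 (2 h triptolide, p = 0.1) and 0.00096 (2 h DRB, p = 1.0).

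Some gene lists stood apart from the other genes with the preset correlation and lost this with an estimated one. With triptolide, in unbound nascent samples, p53 targets had a median of 0.15 (2 of 20 higher, camera adjusted p = 0.021, 0.38 with an estimated correlation) and housekeeping genes -0.19 (2 of 24 lower, 0.0092 and 0.29). With DRB in the nascent samples the unbound histone genes had 0.15 (2 of 57 higher, 3.5e-06 and 0.46), and olfactory receptor genes also stood apart (0.0017 and 0.064). With DRB at 2 h unbound ribosomal protein genes had 0.19 (4 of 81 higher and 2 lower, 2.6e-05 and 0.41), immediate early genes 0.16 (2 of 23 higher, 0.010 and 0.41), pluripotency genes -0.09 (1 of 34 lower, 0.040 and 0.41) and histone genes -0.15 (1 of 57 lower, 0.016 and 0.57). Between 2 h and nascent unbound samples ribosomal protein genes had -0.16 (none called, 0.00022 and 0.73). The difference of DRB effects, 2 h against nascent, had medians of 0.47 for immediate early genes (1 of 23 higher, 0.048 and 0.15), 0.50 for p53 targets (0.035 and 0.15), 0.46 for housekeeping genes (0.042 and 0.15) and 0.30 for Polycomb-bound regulators (0.046 and 0.35). Between EdU and unbound fractions 2-cell-like markers stood apart for nascent triptolide (0.045 and 0.16), and for nascent DRB ribosomal protein genes (median -0.40, 1 of 81 lower, 0.013 and 0.20) and fibroblast markers (median 0.38, 0.026 and 0.079).

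Olfactory receptor genes kept a call with an estimated correlation in the unbound fraction with triptolide at 2 h (14 of 1006 higher and 2 lower, median 0.02, camera adjusted p = 1.1e-05 and 0.0089). Between EdU and unbound fractions they kept one for nascent triptolide (2.0e-09 and 3.8e-06), nascent DRB (4.1e-05 and 0.00033), 2 h triptolide (3.6e-09 and 3.6e-06) and 2 h DRB (0.00044 and 0.0014). No hypothesis was tested on these values.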
